A study of Homo sapiens with 9 samples.

How the data were processed

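RNA-seq counts from 9 libraries of U937-Cas9 cells were used. U937 is an established human monocytic cell line, and the Cas9 in its name is the nuclease used to make gene knockouts. Per the labels, 3 libraries came from WT cells, 3 from cells with an IRF2 knockout (IRF2KO) and 3 from knockout cells that carry pIRF2 (IRF2KO_pIRF2). The labels do not say what pIRF2 encodes, and they do not say how the IRF2 locus was edited. Per the labels' protocols, RNA was purified with a Macherey Nagel kit and libraries were made with the SENSE mRNA-Seq kit of Lexogen. The labels do not say that replicates were separate cultures. Every p-value of a gene test therefore measures only the spread between these samples, which may be technical.

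The deposited values are the authors' raw read counts per gene, not normalised, in 1 table with a column per library. Per the submitters' processing notes, the tools were Bowtie2 2.3.3, TopHat2 2.1.1, SAMtools, bedtools and HTSeq 0.9.1, with the hg38 build. The role of each tool, the gene annotation release, the strand setting and the treatment of reads on overlapping genes are not given in the sources used here. Reads from overlapping or near-identical genes can therefore have been split or dropped in ways that cannot be seen here. The table held 20265 Ensembl gene identifiers, of which 20012 matched GENCODE 29 after their version numbers were removed, 19475 of them protein-coding and 408 immune receptor segments. The other 253 identifiers took 0.0123% of all counts. No count was recorded in any library for 5317 genes, among them 18 pseudoautosomal copies. Symbols, coordinates, GC content and exonic overlaps were taken from GENCODE 29 on GRCh38, the assembly that hg38 names. Coordinates are counted from 1.

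Library totals ranged from 14824907 to 23108288 counts. The floor of detection was set at 3 counts, which is 0.129 to 0.196 CPM (counts scaled to a common library size) in a single library. Floors and intervals cover counting error only, because the reads carry no stated molecular identifiers. Where a gene had 0 counts in every library of a group, its fold is given as a bound against 3 counts over the whole group.

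Counts were filtered with filterByExpr, scaled with TMM factors and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with all 9 libraries in 1 fit and no covariate. All 3 pairs of groups were compared over 11517 genes. Adjusted p-values are Benjamini-Hochberg adjusted, with a threshold of 0.05. Levels are means ± SD of TMM-normalised CPM (n = 3), and log2 fold changes carry their standard errors (SE). A gene was called reverted when it passed the test in IRF2KO against WT and, with the opposite sign, in IRF2KO_pIRF2 against IRF2KO. Because these comparisons share the IRF2KO libraries, 20 data sets with no group effect were simulated to give the chance values, and 20 more for the libraries left without both ends of the first principal component. Each gene was drawn independently in them, so they hold no structure between libraries beyond their sizes.

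Of 26 gene lists, 23 had at least 3 tested members and were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists. They covered the interferon regulatory factors, inflammatory caspases and pyroptosis, guanylate-binding proteins, type I interferon-stimulated genes, interferon gamma genes, interferon receptors and signalling, MHC class I and class II presentation, Toll-like receptor and LPS sensing, cytosolic nucleic acid sensing, NF-kB cytokines and chemokines, apoptosis regulators, primary granules, monocyte maturation, proliferation, the integrated and ER stress responses, hypoxia and glycolysis, cholesterol synthesis, heat shock, mitochondrially encoded genes, replication histones, nuclear retained noncoding RNAs, and markers of T and NK cells, B cells, erythroid cells and megakaryocytes, and epithelial cells and fibroblasts. Camera compares the genes of a list with all other tested genes, so at the preset correlation genes act almost as replicates. Its p-values are therefore not a measure of the spread between samples alone. Counts of members past the gene test are given over all tested genes and adjusted over the list alone. The groups, the tests, the lists and the rule for named genes were fixed before the data were examined.

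The rule named IRF2, then CASP1, CASP4, CASP5, GSDMD, IRF1 and IRF9 whatever their result. It added, per comparison, up to 8 genes with the largest rises and 8 with the largest falls among genes past the test with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries. It also took up to 4 called members per list, up to 6 reverted genes per direction and up to 6 genes that stayed changed in the libraries labelled pIRF2. Other genes are said to have been chosen after their values were seen. Results for some genes are not reported here.

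The fit was tested on simulated counts with 50 genes changed at each of several folds. Each gene was again drawn independently, without the structure between the real libraries, so the results may be too favourable. For IRF2KO against WT it recovered 18% of changes of 1.5-fold, 88% of changes of 2-fold and 100% of changes of 4-fold, with 4 false calls. The shares were 38%, 76% and 100% for IRF2KO_pIRF2 against IRF2KO, with 11 false calls, and 32%, 74% and 98% for IRF2KO_pIRF2 against WT, with 6 false calls.

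Alternatives chosen beforehand were RLE and upper-quartile scaling, no filter on low counts, a minimum of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit with the replicate number as a block, fits of only the groups compared, a test against a fold of 1.5, camera with an estimated correlation, fry, and leaving out each library in turn. Chosen after seeing the data were leaving out both libraries at the ends of the first principal component, adding the share of mitochondrial counts (libraries under or over 15%) as a term, fits of only the libraries on each side of that share, and removing each library's trend with GC content and length. Tables and plots were made in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.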

Results

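Gene-level RNA-seq counts were compared between WT U937-Cas9 monocytic cells, IRF2KO cells and IRF2KO cells labelled as carrying pIRF2, with 3 libraries in each group. The WT libraries held 19172987, 14824907 and 19956617 counts, the IRF2KO libraries 16884085, 20497549 and 17869337, and the libraries labelled pIRF2 23108288, 20539038 and 21276396 (replicates 1 to 3 in each group). Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.974 to 0.996 within groups and 0.939 to 0.993 between groups. Every pair of replicates differed by more than counting noise, with a chi-square per degree of freedom of 3.13 to 93.6. WT replicate 1 and IRF2KO replicate 2 lay at the ends of the first principal component, with scores of -36.1 and 52.3, and WT replicate 3 lay nearest to the libraries labelled pIRF2 on the second. Mitochondrially encoded genes took 12.7%, 12.9% and 17.1% of counts in the WT libraries, 12.2%, 18.8% and 18.0% in the IRF2KO libraries and 17.3%, 17.3% and 18.0% in the libraries labelled pIRF2.

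**Figure D1:**
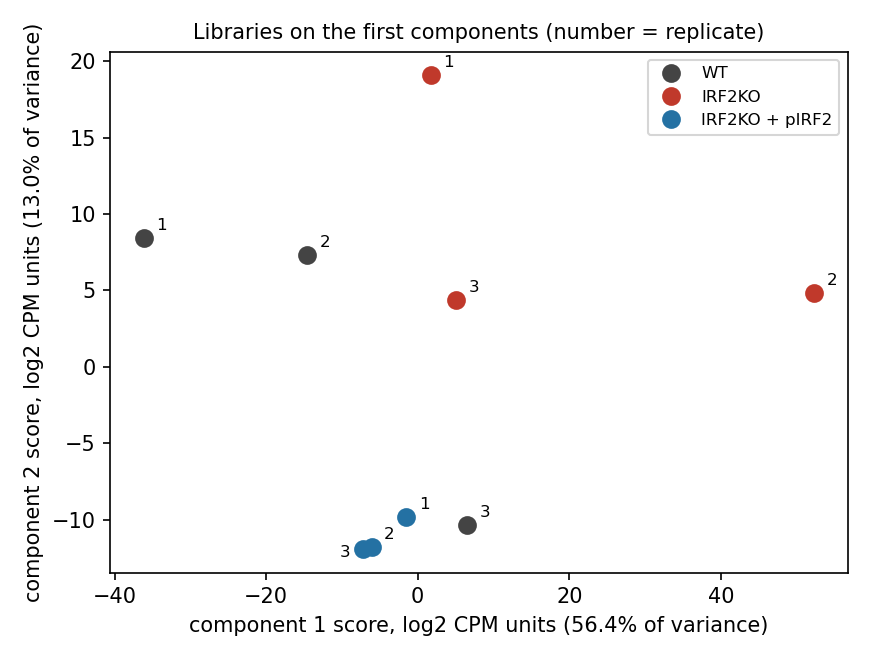
Each point is a library, placed by its scores (log2 CPM units) on the first component (x axis, 56.4% of the variance) and the second component (y axis, 13%), coloured by group and numbered by replicate. WT replicate 1 (-36.1) and IRF2KO replicate 2 (52.3) stand at the ends of the first component.

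IRF2, the targeted gene, encodes a DNA-binding transcription factor of the interferon regulatory factor family (chromosome 4, 184387713 to 184474580, minus strand). Its level was 37.1, 39.1 and 44.1 CPM in WT replicates 1 to 3, 23.5, 25.9 and 25.5 CPM in the IRF2KO libraries, and 15.2, 18.1 and 18.4 CPM in the libraries labelled pIRF2. IRF2 fell in IRF2KO against WT by 0.68 ± 0.13 on the log2 scale (1.61-fold; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.043). It was not raised in the libraries labelled pIRF2, where the log2 fold change was -0.53 ± 0.13 against IRF2KO (edgeR adjusted p = 0.24; 0.023 by DESeq2, and -0.65 ± 0.13, 0.042 after GC and length trends were removed) and IRF2 lay below WT by 2.32-fold (-1.22 ± 0.13, adjusted p = 0.0029). Transcripts of an edited locus can still be counted at IRF2, so these counts do not show whether the protein was lost. The counts lack the rise at IRF2 that the name pIRF2 could imply, but transcripts of a construct may not be counted there. They therefore do not decide whether the label is right, and every direction given for that group rests on its label. The IRF2 call against WT was lost without WT replicate 1 (edgeR adjusted p = 0.061), WT replicate 2 (0.20), WT replicate 3 (0.11), IRF2KO replicate 1 (0.16), IRF2KO replicate 3 (0.12) or replicates 1, 2 and 3 labelled pIRF2 (0.071, 0.10 and 0.098), with log2 fold changes of -0.74 to -0.61. It was also lost with only the WT and IRF2KO libraries in the fit (0.22), after GC and length trends were removed (-0.53, 0.092) and in fits of only the libraries under or over 15% mitochondrial counts (-0.68, 0.46 and -0.79, 0.66).

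**Figure D2:**
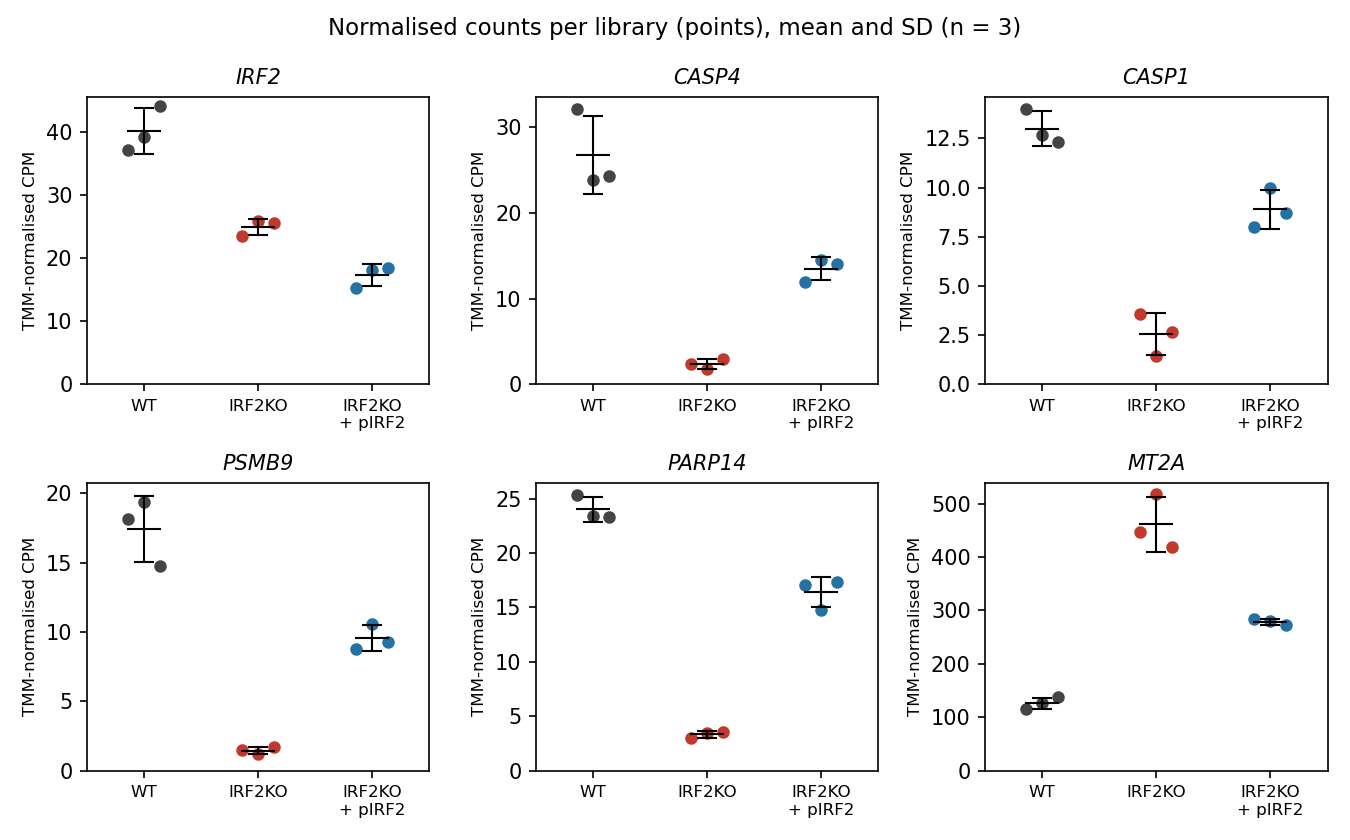
TMM-normalised CPM (y axes, each from 0) of IRF2, CASP4, CASP1, PSMB9, PARP14 and MT2A in each library (points) of the WT, IRF2KO and pIRF2-labelled groups (x axes), with the group mean and SD (bars, n = 3). CASP4, CASP1, PSMB9 and PARP14 were lowest in IRF2KO and intermediate in the libraries labelled pIRF2, MT2A was highest in IRF2KO, and IRF2 was lowest in the libraries labelled pIRF2.

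The comparison of IRF2KO with WT cells asks which transcripts depend on the IRF2 locus. In IRF2KO cells, 3 of 17 tested inflammatory caspase and pyroptosis genes, 15 of 42 type I interferon-stimulated genes and 5 of 20 genes of MHC class I presentation fell, and 0 of these rose. CASP4, the caspase that senses cytosolic lipopolysaccharide, fell 11.3-fold, from 26.8 ± 4.60 to 2.38 ± 0.584 CPM, and CASP1, which matures interleukin-1 beta, fell 5.14-fold, from 13 ± 0.889 to 2.55 ± 1.08 CPM. PSMB9, a catalytic subunit of the immunoproteasome, fell 12.1-fold, and PARP14, an interferon-inducible ADP-ribosyltransferase, fell 7.23-fold. MT2A, a metal-binding metallothionein, rose 3.66-fold, from 126 ± 10.6 to 462 ± 51.8 CPM.

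By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 48 of 11517 genes changed, 6 rising and 42 falling, and 42 of them differed by more than 2-fold. An unadjusted p under 0.05 was reached by 2149 genes, where 576 would be expected by chance. This excess cannot be credited to the knockout alone. A split of the same libraries by mitochondrial share, not by group, called 483 genes. After GC and length trends were removed, 107 genes passed, 40 rising and 67 falling, and DESeq2 called 114, 47 rising and 67 falling. With the mitochondrial share of counts as a term, 49 genes passed, 46 of them among the 48. Among the 3 libraries under 15% mitochondrial counts (WT replicates 1 and 2 and IRF2KO replicate 1) 38 genes passed, 34 of them among the 48, and among the 6 over 15%, with WT replicate 3 alone for WT, 26 passed, 25 of them among the 48. The sign was that of the full fit for all 47 of the 48 tested under 15% and all 48 over it. These genes were called in a fit that held the same libraries, so this agreement was largely fixed in advance and is not independent support. A lone library was assumed to vary like the other groups. Without both libraries at the ends of the first component, 61 genes passed, 44 of them among the 48.

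The largest falls among genes with at least 5 CPM were those of ERAP2, an aminopeptidase that trims peptides for MHC class I (34.1-fold, from 5.16 ± 1.31 to 0.147 ± 0.0394 CPM), GIMAP2, a GTPase of immune cells (22-fold), and SAMD9, an antiviral factor (20.1-fold). They had edgeR quasi-likelihood, Benjamini-Hochberg adjusted p-values of 2.0e-05, 2.0e-05 and 5.0e-06. ERAP2 had 3, 2 and 3 counts in IRF2KO replicates 1 to 3, at or below the floor of 3 counts, so its fold is imprecise. BTN3A3, a butyrophilin, fell 8.21-fold. Reads of BTN3A3, BTN3A1 and BTN3A2, which have similar sequences, may have been split between them or lost by the counting. MT2A had the largest rise the rule named (log2 fold change 1.87 ± 0.11, edgeR adjusted p = 4.3e-06). It also named LSP1, an actin-binding protein of leukocytes (0.94 ± 0.17, adjusted p = 0.044), and SIRPB1, a myeloid signalling receptor (0.78 ± 0.13, adjusted p = 0.029), whose exons overlap another annotated gene over 13.4% of their length. The LSP1 call was lost without WT replicates 1 or 2, IRF2KO replicate 1 or any replicate labelled pIRF2 (edgeR adjusted p = 0.085 to 0.23), with only the 2 groups in the fit (0.23) and by limma-voom (0.052). The SIRPB1 call was lost without any WT replicate, IRF2KO replicate 3 or any replicate labelled pIRF2 (0.077 to 0.22), and with only the 2 groups in the fit (0.22). ANXA2R, named for annexin A2 binding, fell 3.92-fold (edgeR adjusted p = 5.6e-04).

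Of 17 tested genes of the inflammatory caspase and pyroptosis list, 0 rose, 3 fell and 14 did not pass, and 0 rose and 4 fell when adjusted over the list alone (camera adjusted p = 3.9e-07). The median log2 fold change of the list was -0.08 and the mean -0.86, with 6 members higher and 11 lower. The 3 that fell, CASP4, CASP1 and CARD16, lie side by side on chromosome 11, so the list call need not reflect the rest of the list. CASP4 (chromosome 11, 104942866 to 104969436, minus strand) had a log2 fold change of -3.50 ± 0.21 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 4.3e-06) and CASP1 (chromosome 11, 105025443 to 105035250, minus strand) -2.36 ± 0.25 (adjusted p = 5.6e-04). CARD16, which shares its CARD sequence with CASP1 and can share reads with it, had 0 counts in the IRF2KO libraries and 105 in WT, at least 35.6-fold lower. GSDMD, the pore-forming substrate of both caspases, had a log2 fold change of 0.28 ± 0.21 (adjusted p = 0.40). Its sign turned when both end libraries were left out (-0.15) or GC and length trends were removed (-0.16). CASP5 had 0 counts in all 9 libraries. In the apoptosis list, 0 of 28 rose, 1 fell and 27 did not pass (0 and 1 adjusted over the list alone; camera adjusted p = 0.58).

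Of 42 tested type I interferon-stimulated genes, 0 rose, 15 fell and 27 did not pass, and 7 rose and 26 fell when adjusted over the list alone (camera adjusted p = 7.5e-35). The members with the smallest p were PARP14 (log2 fold change -2.85 ± 0.15, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.8e-06), UBE2L6, the conjugating enzyme of the ubiquitin-like protein ISG15 (-2.21 ± 0.13, 4.3e-06), SAMD9 (-4.33 ± 0.27, 5.0e-06) and DTX3L, a ubiquitin ligase (-1.53 ± 0.12, 2.7e-05). UBA7, the activating enzyme for ISG15, fell 6.04-fold, OAS3, an oligoadenylate synthetase, 6.59-fold and IFIH1, a sensor of double-stranded RNA, 5.50-fold (edgeR adjusted p = 8.3e-05, 3.9e-04 and 5.3e-05). Members moved in both directions. The 7 genes that rose when adjusted over the list alone included, chosen after their values were seen, IFIT2 (1.51 ± 0.37), ISG15 (0.57 ± 0.23), ZNFX1 (0.53 ± 0.12), BST2 (0.50 ± 0.10), STAT2 (0.47 ± 0.20) and IFITM2 (0.32 ± 0.14). Of the 7, 0 passed over all genes.

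Of 20 tested genes of MHC class I presentation, 0 rose, 5 fell and 15 did not pass, and 1 rose and 9 fell when adjusted over the list alone (camera adjusted p = 2.1e-16). PSMB9 (chromosome 6, 32844136 to 32859585, plus strand) fell from 17.4 ± 2.41 to 1.44 ± 0.265 CPM (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.9e-06), and 4.5% of its exonic length overlaps PSMB8 on the opposite strand. PSME1, a proteasome activator subunit, fell 2.29-fold (-1.20 ± 0.09, edgeR adjusted p = 2.7e-05), and ERAP1, the neighbouring aminopeptidase of ERAP2, fell 2.73-fold (adjusted p = 0.0015). PSME2, the partner of PSME1 and chosen after its values were seen, was the fifth member to fall (-0.69 ± 0.10, adjusted p = 0.0058). Its call was lost without WT replicate 2 (0.060) and with only the 2 groups in the fit (0.11).

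With an estimated inter-gene correlation the calls of these 3 lists held, at much larger camera adjusted p-values. These were 0.0083 for caspases and pyroptosis, 1.3e-04 for type I genes and 0.0022 for MHC class I. The calls of the other 5 lists past the threshold did not hold. Among guanylate-binding proteins, 0 of 5 rose, 1 fell and 4 did not pass (0 and 1 adjusted over the list alone). The gene was GBP3, an interferon-induced GTPase (-3.72 ± 0.49, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0033). It had 1, 2 and 3 counts in IRF2KO replicates 1 to 3, at or below the floor, so the size of its fall is imprecise. The list had a camera adjusted p = 0.040, and adjusted p = 0.23 with an estimated correlation. Monocyte maturation genes (28 tested; camera adjusted p = 0.033, and adjusted p = 0.59 with an estimated correlation), mitochondrially encoded genes (13; 0.036, and adjusted p = 0.68 with an estimated correlation), replication histones (12; 0.033, and adjusted p = 0.68 with an estimated correlation) and B-cell markers (4; 0.033, and adjusted p = 0.38 with an estimated correlation) lay higher in IRF2KO, with 0 members past the test over all genes. Adjusted over the list alone, 1, 0, 0 and 2 members of these lists rose and 0 fell. The mitochondrial share of counts was 12.7%, 12.9% and 17.1% in the WT libraries and 12.2%, 18.8% and 18.0% in the IRF2KO libraries. Leaving out 1 library ended the call of the guanylate-binding proteins (WT replicate 2, camera adjusted p = 0.075; WT replicate 3, 0.088; IRF2KO replicate 2, 0.080; IRF2KO replicate 3, 0.16), monocyte maturation (WT replicate 1, 0.057; IRF2KO replicate 2, 0.11), mitochondrial genes (WT replicate 2, 0.22; IRF2KO replicate 2, 0.18; IRF2KO replicate 3, 0.28), histones (WT replicate 3, 0.57; IRF2KO replicate 1, 0.12; IRF2KO replicate 3, 0.20) and B-cell markers (WT replicate 2, 0.057; IRF2KO replicate 3, 0.056). The count of 8 lists became 5 without WT replicate 2 and 4 without IRF2KO replicate 3. Without both end libraries the calls of the guanylate-binding proteins (camera adjusted p = 0.085), monocyte maturation (0.57), mitochondrial genes (0.46) and B-cell markers (0.14) ended. After GC and length trends were removed, those of the guanylate-binding proteins (0.075), monocyte maturation (0.075) and B-cell markers (0.12) ended, and with the mitochondrial share as a term those of the guanylate-binding proteins (0.075) and mitochondrial genes (0.41). Among the libraries under 15% mitochondrial counts all 5 of these calls ended (guanylate-binding proteins 0.084, monocyte maturation 0.053, histones 0.35, B-cell markers 0.058, and mitochondrial genes, which lay lower there, 0.82). Among those over 15%, monocyte maturation (0.062) and B-cell markers (0.081) ended.

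The other 15 tested lists did not pass with all libraries and no covariate. Cholesterol synthesis, higher in IRF2KO, did pass without both end libraries (camera adjusted p = 7.6e-04), with the mitochondrial share as a term (0.022), after GC and length trends were removed (2.5e-04), without WT replicate 1 (0.032) or IRF2KO replicate 2 (0.0022), and by fry (0.0018). Interferon gamma genes, lower in IRF2KO, passed in the same 6 settings (0.0083, 0.045, 0.014, 0.027, 0.019 and 0.0093). Without both end libraries the interferon regulatory factors lay lower (0.0062) and heat shock genes higher (1.4e-04), the latter also without IRF2KO replicate 2 (0.014), and apoptosis genes lay lower by fry (0.020). Cholesterol synthesis also passed among the libraries under 15% mitochondrial counts (0.014; 0.14 over 15%), and NF-kB cytokines lay higher among those over 15% (0.037; 0.70 and lower under 15%). Of 7 interferon regulatory factor genes, 0 rose, 1 fell (IRF2) and 6 did not pass, with 2 falling when adjusted over the list alone (camera adjusted p = 0.63). IRF1, the family member that binds the same DNA elements, stood at 6.38 ± 1.68 CPM in WT and 8.23 ± 0.546 CPM in IRF2KO (0.36 ± 0.19, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.28), with 22% of its exonic length overlapped on the opposite strand. IRF9, a DNA-binding factor of type I interferon signalling, had 0 counts in all 9 libraries, and 48.4% of its exonic length is shared with an overlapping annotated gene. Of 12 interferon gamma genes, 0 rose, 1 fell (APOL2, 12.4-fold, edgeR adjusted p = 2.3e-04) and 11 did not pass, with 0 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.091). No member passed over all genes in the lists of interferon receptors and signalling (camera adjusted p = 0.67), MHC class II (0.69), Toll-like receptors (0.75), nucleic acid sensing (0.19), NF-kB cytokines (0.69), primary granules (0.31), proliferation (0.55), integrated and ER stress (0.75), hypoxia (0.67), cholesterol synthesis (0.061), heat shock (0.47) and T and NK cells (0.69). Adjusted over the list alone, 1 gene rose and 1 fell in nucleic acid sensing, 1 rose in cholesterol synthesis and 0 changed in the other 10. For the interferon regulatory factors and the apoptosis list, the median log2 fold change was above 0 (0.04 and 0.02) while the mean (-0.10 and -0.04) and the test pointed down. With 2 tested members each, the lists of erythroid cells and megakaryocytes and of epithelial cells and fibroblasts were not tested, and 0 of their members passed over all genes, with 1 erythroid or megakaryocyte gene rising when adjusted over the list alone; the nuclear retained RNAs have 0 entries in the table.

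**Figure D3:**
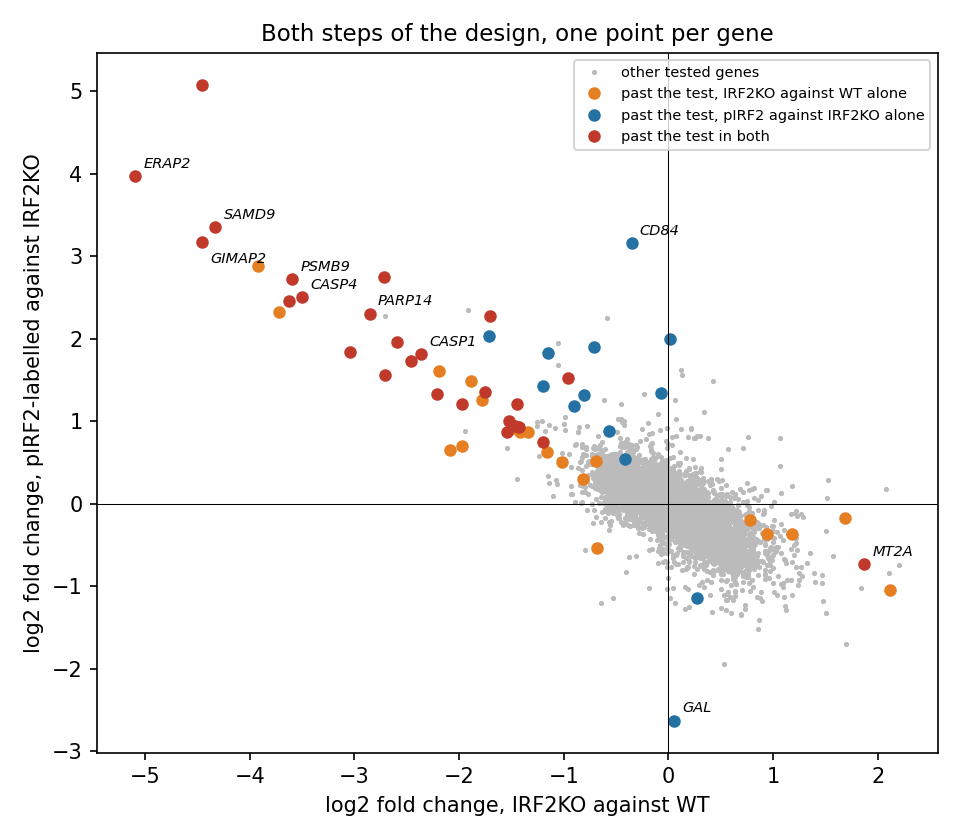
Each point is a tested gene (11514 genes; genes with 0 counts in a group are left out), with the log2 fold change of IRF2KO against WT on the x axis and of the pIRF2-labelled group against IRF2KO on the y axis, coloured by the test each gene passed. Genes past both tests (26 plotted) lie at the upper left (ERAP2 at -5.09, 3.97), except MT2A at the lower right (1.87, -0.73); both axes share the IRF2KO libraries, which by itself tilts the cloud downward.

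The comparison of the libraries labelled pIRF2 with IRF2KO asks which of these transcripts return in the knockout cells labelled as carrying pIRF2. In these libraries 3 of 17 caspase and pyroptosis genes, 10 of 42 type I interferon-stimulated genes and 5 of 20 MHC class I genes rose, and 0 of these fell over all genes. CASP4 rose 5.68-fold, to 13.5 ± 1.35 CPM, and CASP1 3.51-fold, to 8.89 ± 1.0 CPM. PSMB9 rose 6.62-fold, to 9.55 ± 0.941 CPM, PARP14 4.94-fold, to 16.4 ± 1.41 CPM, and ERAP2 15.7-fold, to 2.38 ± 0.558 CPM. The ERAP2 fold again rests on IRF2KO counts at or below the floor. MT2A fell 1.66-fold, to 279 ± 5.67 CPM.

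By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 42 genes changed, 39 rising and 3 falling, 35 of them by more than 2-fold, and 1291 genes had an unadjusted p under 0.05. Without replicate 2 labelled pIRF2 the count was 26; with GC and length trends removed it was 65, and by DESeq2 64. With the mitochondrial share as a term, 54 genes passed, all 42 among them. Among the 6 libraries over 15% mitochondrial counts 31 passed, 29 of them among the 42. The largest rises of the rule, with edgeR adjusted p-values, were those of PARP14 (2.3 ± 0.15, 3.9e-05), OAS3 (2.76 ± 0.28, 6.3e-04), PSMB9 (2.73 ± 0.20, 8.6e-05), CASP4 (2.50 ± 0.21, 1.7e-04) and UBA7 (1.97 ± 0.22, 0.0016). SAMD9 rose 10.2-fold (edgeR adjusted p = 1.7e-04), GIMAP2 9.0-fold (8.5e-04) and BTN3A3 3.57-fold (0.0034). CASP1 (1.81 ± 0.25, edgeR adjusted p = 0.0067) was no longer called without IRF2KO replicate 3 (0.056) or replicate 2 labelled pIRF2 (0.057).

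Of 42 type I interferon-stimulated genes, 10 rose, 0 fell and 32 did not pass, with 21 rising and 1 falling when adjusted over the list alone (camera adjusted p = 4.7e-36). In the MHC class I list, 5 of 20 rose, 0 fell and 15 did not pass (6 and 0 adjusted over the list alone; camera adjusted p = 1.1e-14), among them PSME1 (0.75 ± 0.09, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0018) and ERAP1 (1.21 ± 0.17, adjusted p = 0.0077; 0.061 without replicate 2 labelled pIRF2). In the caspase list, 3 of 17 rose, 0 fell and 14 did not pass (3 and 0 adjusted over the list alone; camera adjusted p = 8.9e-07), the third being CARD16, with 73 counts against 0, at least 20.8-fold higher. The caspase list had a median log2 fold change of 0.27 and a mean of 0.77, and its 3 called genes are neighbours. The calls of all 3 lists held with an estimated correlation (camera adjusted p = 1.2e-04 for type I genes, 0.0034 for MHC class I and 0.0096 for the caspase list). The other 20 lists did not pass. Among these, the median, the mean and the test differed in sign for interferon gamma genes, MHC class II, NF-kB cytokines, hypoxia and heat shock. This count of 3 lists became 5 without WT replicate 2 and 6 without IRF2KO replicate 2 or replicate 3 labelled pIRF2. Monocyte maturation genes lay higher than in IRF2KO without IRF2KO replicate 2 (camera adjusted p = 0.0021), without both end libraries (0.0048) and after GC and length trends were removed (0.0074), and mitochondrial genes in the first 2 of these (0.0044 and 0.0062). Replication histones lay lower without IRF2KO replicate 2 (0.034) or replicate 3 labelled pIRF2 (0.023), and guanylate-binding proteins higher without WT replicate 2 (0.048) or replicate 3 labelled pIRF2 (0.023). The interferon regulatory factors lay lower without replicate 2 labelled pIRF2 (0.046). By fry, guanylate-binding proteins (0.045) and apoptosis genes (0.0061) lay higher and stress genes lower (0.021). Epithelial and fibroblast markers, with 2 tested members, had 0 past the test over all genes, and 2 rose when adjusted over the list alone. With 3 members in some smaller fits, this list lay higher without WT replicate 2 (camera adjusted p = 0.024) or replicate 3 labelled pIRF2 (0.023). It did not pass without WT replicates 1 or 3, IRF2KO replicates 1 or 3 or replicate 2 labelled pIRF2 (0.053 to 0.44), or among the libraries over 15% mitochondrial counts (0.16). APOL2, an apolipoprotein L of the interferon gamma list (2.46 ± 0.37, edgeR adjusted p = 0.013), was lost without IRF2KO replicates 1 or 3 or replicates 1 or 2 labelled pIRF2 (0.057 to 0.080). FCGR2B, an inhibitory Fc receptor with near-identical paralogs, rose from 1.60 to 4.10 CPM (1.35 ± 0.21, edgeR adjusted p = 0.014). Its call was lost without IRF2KO replicates 1 or 3 or replicates 1 or 3 labelled pIRF2 (0.084 to 0.11). GBP3 did not pass (2.33 ± 0.57, edgeR adjusted p = 0.26).

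Joining both steps, 28 genes passed with opposite signs: 27 fell in IRF2KO and rose in the libraries labelled pIRF2, where independent lists of these sizes would share 0.142, and MT2A rose and fell again, where 0.00156 would be expected. The 6 reverted genes with the smallest larger p were PARP14, PSMB9, CASP4, SAMD9, UBE2L6 and OAS3. The simulation with unchanged groups gave 0 reverted genes in each of 20 runs. Its genes were drawn independently, without the structure between the real libraries, and regroupings of the real libraries gave up to 5. Of the 48 genes changed in IRF2KO, 47 had the opposite sign in the second step and 42 had a mean between WT and IRF2KO in the libraries labelled pIRF2. Opposite signs were held by 84.3% of all tested genes and, from the shared libraries alone, by 66.8% in the simulation. The median share of the log2 change returned was 70.6% over the 42 lowered genes and 75.8% over the 27 reverted ones, and the same values were found with CARD16 and SAMD9L, which had 0 counts in IRF2KO, set at their bounds. This share compares changes that both use the IRF2KO mean, in genes selected on the first of them. Over all genes, which are not independent, the log2 fold changes of the steps had a Pearson correlation of -0.788, against -0.507 in the simulation. They had a covariance of -0.106, against -0.0243, a difference of -0.0817. Without both end libraries, 1 of them an IRF2KO library, the covariance was -0.0611, against -0.0204 in a simulation of the libraries left, a difference of -0.0407, and the correlation was -0.665, against -0.561. The simulated values already include the shared IRF2KO libraries, but not the structure between the real libraries. Part of the excess may come from that structure. Taken under and over 15% mitochondrial counts, the first and second step shared no IRF2KO library (replicate 1, then replicates 2 and 3). Log2 fold changes were then -3.58 and 2.50 (CASP4), -1.89 and 2.14 (CASP1), -3.65 and 2.75 (PSMB9) and -3.03 and 2.24 (PARP14). They were -5.02 and 4.10 (ERAP2), 1.90 and -0.74 (MT2A) and -0.68 and -0.57 (IRF2). Of these genes, all but IRF2 reversed. The genes that reversed had already been called reverted with all libraries, so their reversal here is not independent support. The MT2A call in the second step (-0.73 ± 0.11, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.013) was lost without any replicate labelled pIRF2 (0.084 to 0.12).

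The comparison of the libraries labelled pIRF2 with WT asks what still differed. IRF2 itself, ANXA2R, BTN3A1 and UBE2L6 stayed below WT, and MT2A stayed above it, at 279 ± 5.67 against 126 ± 10.6 CPM (log2 fold change 1.14 ± 0.11, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0022). BTN3A1 stood at 10.4 against 23.1 CPM (-1.15 ± 0.15, edgeR adjusted p = 0.011), UBE2L6 at 74.0 against 136 CPM (-0.88 ± 0.13, 0.029) and ANXA2R at 2.22 against 5.40 CPM (-1.27 ± 0.20, 0.048). CASP4 (-0.99 ± 0.18, edgeR adjusted p = 0.091), PSMB9 (-0.87 ± 0.16, 0.11) and CASP1 (-0.55 ± 0.23, 1) did not pass. CASP4 and PSMB9 were called below WT, at about the same fold, without both end libraries (-0.84 ± 0.12, edgeR adjusted p = 0.0049, and -0.83 ± 0.14, 0.022), after GC and length trends were removed (-0.93 ± 0.11, 0.0014, and -0.83 ± 0.12, 0.0076), without IRF2KO replicate 2 (0.010 and 0.024) and by DESeq2 (1.2e-04 and 8.7e-04). CASP4 was also called with no filter on low counts (0.038) and with only the 2 groups in the fit (0.030). Other genes lowered in IRF2KO, chosen after their values were seen, were called without both end libraries and after trends were removed. GIMAP2, BTN3A3, BTN3A2, APOL2, UBA7, DTX3L, PSME1 and HERC6 lay below WT (edgeR adjusted p = 0.0016 to 0.038 and 0.0014 to 0.033). SAMD9L lay above WT (1.76 ± 0.26, edgeR adjusted p = 0.0064, and 1.68 ± 0.20, 0.0041). The other 4 calls, chosen after their values were seen, were CD84 and CD52, surface proteins of leukocytes, and RORB, a nuclear receptor, which rose to 3.13, 4.05 and 3.29 CPM (2.81 ± 0.26, 1.87 ± 0.21 and 2.02 ± 0.26; edgeR adjusted p = 0.0022, 0.0041 and 0.011), and GAL, the galanin neuropeptide, which fell by 2.57 ± 0.33 on the log2 scale (0.011).

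By edgeR, 9 genes changed, 4 rising and 5 falling, and 452 had an unadjusted p under 0.05, where 576 would be expected by chance. The count was 25 without IRF2KO replicate 2, 3 without WT replicate 2 and 4 without any replicate labelled pIRF2. It was 27 without both end libraries, 43 with GC and length trends removed and 37 by DESeq2. Among the 6 libraries over 15% mitochondrial counts, 1 of them WT, all 9 called genes had the sign of the full fit. That fit held the same libraries, so this agreement is not independent support. With 1 WT library, the smaller fit cannot show that the calls hold. Leaving out 1 library ended the call of BTN3A1 (WT replicate 2 or any replicate labelled pIRF2; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.076 to 0.16), of UBE2L6, RORB and GAL (WT replicates 2 or 3 or any replicate labelled pIRF2; 0.082 to 0.32, 0.067 to 0.13 and 0.055 to 0.13), of ANXA2R (any WT replicate, IRF2KO replicate 3 or any replicate labelled pIRF2; 0.094 to 0.36) and of CD52 (WT replicate 2; 0.061). The ANXA2R call also ended with the mitochondrial share as a term (0.082) and with the 1 CPM minimum (0.052).

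Camera called 9 lists, and 0 of them held with an estimated correlation (adjusted p = 0.11 with an estimated correlation for each, except 0.19 for the mitochondrial genes). Below WT lay the interferon regulatory factors (0 of 7 rose, 1 fell, 6 did not pass; camera adjusted p = 5.6e-05), type I interferon-stimulated genes (0 of 42 rose, 1 fell, 41 did not pass; 0.0022), MHC class I (0.0026), interferon gamma genes (0.026) and integrated and ER stress genes (0.030), the last 3 with 0 members past the test. Adjusted over the list alone, 0 and 3, 2 and 7, 0 and 3, 0 and 1 and 0 and 0 members of these lists rose and fell. Above WT lay monocyte maturation (1.5e-08), mitochondrially encoded genes (2.0e-07), B-cell markers (9.1e-04) and cholesterol synthesis (0.029), with 0 members past the test; adjusted over the list alone, 1, 0, 1 and 0 rose and 0 fell. Mitochondrial counts took 17.3%, 17.3% and 18.0% in the libraries labelled pIRF2 and 12.7%, 12.9% and 17.1% in WT, and with that share as a term the B-cell call ended (0.14) and the mitochondrial list turned (0.94). Without WT replicate 3 only 4 lists passed: the interferon regulatory factors (0.16), type I genes (0.085), interferon gamma genes (0.16), MHC class I (0.16), stress genes (0.16) and cholesterol synthesis (0.11) lost their calls. The calls of interferon gamma genes (0.11) and cholesterol synthesis (0.074) were also lost without replicate 3 labelled pIRF2, and that of stress genes without replicate 1 (0.11). Among lists that did not pass, the median, the mean and the test differed in sign for primary granules and hypoxia. Of these lists, caspase and pyroptosis genes lay below WT without both end libraries (camera adjusted p = 0.021), with the mitochondrial share as a term (0.047) and after GC and length trends were removed (0.030). In the first 2 of these settings heat shock genes (0.027 and 0.0072) and replication histones (0.0088 and 0.0012) lay above WT. With 1 library left out, caspase genes (without WT replicates 1 or 2 or replicate 2 labelled pIRF2; 0.039, 0.030 and 0.045), replication histones (the same; 0.0013, 0.014 and 1.4e-04) and T and NK cell markers (higher, without WT replicate 2, IRF2KO replicate 1 or replicate 1 labelled pIRF2; 0.036, 0.019 and 0.048) also passed. By fry, caspase genes lay below WT (0.029) and Toll-like receptor genes above it (0.046). Among the libraries over 15% mitochondrial counts, caspase genes (0.040) and primary granules (0.038) lay below WT and NF-kB cytokines (0.035) and replication histones (3.3e-06) above it. The calls of interferon gamma genes (0.11), stress genes (0.053), mitochondrial genes (0.29), B-cell markers (0.28) and cholesterol synthesis (0.29) ended there.

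Epithelial and fibroblast markers had 2 tested members, too few for camera with all libraries, and both rose against WT when adjusted over the list alone (median log2 fold change 1.48), with 0 past the test over all genes. They were the collagen gene COL1A1, at 0.540 CPM in WT, 0.754 CPM in IRF2KO and 2.15 CPM in the libraries labelled pIRF2 (1.91 ± 0.39 against WT, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.17), and the fibronectin gene FN1 (1.04 ± 0.34, adjusted p = 1), both chosen after their values were seen. After GC and length trends were removed, COL1A1 was called against WT (1.83 ± 0.34, edgeR adjusted p = 0.035) and against IRF2KO (1.81 ± 0.31, 0.015). The list could be tested, and lay above WT, without any WT replicate, IRF2KO replicates 1 or 3 or replicates 2 or 3 labelled pIRF2 (camera adjusted p = 1.9e-06 to 0.0013), and among the 6 libraries over 15% mitochondrial counts (0.0069). In IRF2KO against WT it did not pass in any of these fits (0.46 to 0.85). COL1A2, COL3A1, EPCAM and KRT19 of the same list had 0 counts in all 9 libraries.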

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

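The fits without both end libraries, with the mitochondrial share as a term, with GC and length trends removed and of only the libraries under or over 15% mitochondrial counts were chosen after the data were seen; all others were planned. The gene counts of 48 (IRF2KO against WT), 42 (pIRF2-labelled against IRF2KO) and 9 (pIRF2-labelled against WT), the 28 reverted genes and the 8, 3 and 9 lists stayed within 1.5 times of these values under RLE or upper-quartile scaling, the 1 CPM minimum and limma-voom, where each was run. In the same order of comparisons, DESeq2 called 114, 64 and 37 genes, the GC and length correction 107, 65 and 43, and the test against a fold of 1.5, by its construction stricter, 30, 25 and 1, with 17 reverted. Fits of only the groups compared called 31 genes in the first comparison and 16 in the third. Only the libraries under 15% mitochondrial counts gave 38 genes in the first, and only those over it 26, 31 and 0, with 22 reverted; camera gave 4 lists under 15% in the first, and 7, 3 and 9 over it. The third gave 18 genes with no filter and 27 without the end libraries. Camera with an estimated correlation kept 3 lists in the first comparison and 0 in the third; in the second, fry called 6 lists and camera without the end libraries 5. The cause of these differences was not tested. Leaving out each library gave 34 to 49, 26 to 47 and 3 to 25 genes, 19 to 28 reverted genes, and 4 to 9, 3 to 6 and 4 to 13 lists. GSDMD in IRF2KO against WT turned from 0.28 to -0.15 without the end libraries and -0.16 after the GC and length correction, and the mitochondrial list in the third comparison turned (adjusted p = 0.935) with the mitochondrial share as a term, which is built on its own genes. Of 2115 results of called or named genes under alternatives, 1818 kept their direction and side of the threshold, 295 kept the direction and lost the call, and 2 reversed; 54 of 101 results were the same throughout.

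The replicate numbers did not pair the libraries: same-numbered pairs had deviations correlated at -0.43 to 0.61, 2 of 9 pairs were over 0.1, and 3 of 9 libraries correlated best with their own number. With the replicate block, 39, 36 and 7 genes, 26 reverted genes and 8, 3 and 9 lists passed, and IRF2 in IRF2KO against WT was not called (-0.68, adjusted p = 0.064). Depth limits genes near 3 counts, which is 0.129 to 0.196 CPM per library.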

Other observations

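The gene families and other genes named in this part, the neighbour count and the tests on IRF2 and on B-cell genes were chosen only after results were seen; the GC, length and regrouping tests were planned before theirs.

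Genes lowered in IRF2KO cells often lay side by side. Of the 42, 14 were within 100000 bp of another lowered gene, in 6 clusters: CASP4, CASP1 and CARD16 on chromosome 11, ERAP1 and ERAP2 on 5, PSME1 and PSME2 on 14, BTN3A1, BTN3A2 and BTN3A3 on 6, SAMD9 and SAMD9L on 7, and DDX60 and DDX60L on 4. Among 10000 random draws of as many tested genes the mean was 0.539 and the highest 8 (one-sided permutation p = 1e-04, the smallest they can give). Most of these clusters hold paralogs, which can share reads as well as regulation. Among 5 tested butyrophilin genes, BTN3A1, BTN3A2 (32 to 11 CPM, -1.54 ± 0.14) and BTN3A3 fell and rose again in the libraries labelled pIRF2, while BTN2A1 (-0.11 ± 0.15) and BTN2A2 (-0.03 ± 0.23) did not pass. The BTN3A2 rise (0.87 ± 0.14, edgeR adjusted p = 0.014) was lost without IRF2KO replicates 1 or 3 or replicates 1 or 2 labelled pIRF2 (0.067 to 0.099).

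HERC6, a ubiquitin ligase-family gene (-2.08 ± 0.29, edgeR adjusted p = 0.0053), and USP18, the ISG15 protease (-1.42 ± 0.22, adjusted p = 0.012), fell in IRF2KO. ISG15 stood at 4.78 CPM in WT and 7.04 in IRF2KO (0.57 ± 0.23, adjusted p = 0.26). The USP18 call was lost without IRF2KO replicate 3 (edgeR adjusted p = 0.080). Of 5 tested metallothioneins, MT2A passed, and MT1E (0.66 ± 0.13, adjusted p = 0.065), MT1X (0.37 ± 0.11), MT1F (0.35 ± 0.14) and MT1G (0.19 ± 0.12) did not. MT1E was called after GC and length trends were removed (0.59 ± 0.10, edgeR adjusted p = 0.015) and MT1X without both end libraries (0.49 ± 0.10, 0.031). SAMD9L had 64 counts in WT, 0 in IRF2KO (at least 21.7-fold lower) and 235 in the libraries labelled pIRF2 (at least 67.0-fold higher than IRF2KO). ABI3BP had 0 counts in WT and IRF2KO and 61 in the libraries labelled pIRF2, at least 17.1-fold higher than WT and 17.4-fold higher than IRF2KO. Its call against IRF2KO was lost without IRF2KO replicate 3 or any replicate labelled pIRF2 (edgeR adjusted p = 0.061 to 0.084).

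WT replicate 1 and IRF2KO replicate 2 lay at the ends of the first component, which held 56.4% of the variance. A transcript length trend is argued against by the loadings (rho = -0.0739 with exonic length). They followed GC content (rho = 0.808), consistent with a GC trend between libraries. Removing GC and length trends together took away 37.9% of the total variance and left rho with GC at 0.0710, but both libraries stayed at the ends, at -23.0 and 28.4, so these trends are not the whole pattern. No biological explanation was tested, because both libraries carry their group's labels.

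IRF2 counts were no higher in the libraries labelled pIRF2 (17.3 CPM) than in those labelled IRF2KO (24.9 CPM), although 28 genes reverted. Construct transcripts not counted at IRF2, such as a recoded or shortened sequence, may account for this, and so could exchanged labels of the 2 groups. With exchanged labels the reverted genes would lie nearer to WT in the knockout than in the cells carrying pIRF2. The explanations cannot be told apart here, because the construct's sequence and the edit are not given and these counts decide neither. A lower level of the endogenous transcript in cells carrying pIRF2 remains open and untested.

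CD84, CD52, CD22 and FCGR2B, genes of B cells and some myeloid cells, stood higher in the libraries labelled pIRF2 than in WT, though CD22 and FCGR2B did not pass (edgeR adjusted p = 0.065 for each). Both were called after GC and length trends were removed (1.53 ± 0.24, edgeR adjusted p = 0.012, and 1.27 ± 0.19, 0.0099) and without both end libraries (0.028 and 0.027). B cells or their RNA are argued against: CD79B, MS4A1, IGHM and IGKC together had 2 counts there (upper 95% bound 7.22), against 151 for CD22 (lower bound 128). For CD84 a GC trend is also argued against, since it had a log2 fold change of 2.82 after GC and length trends were removed together and 2.81 before. A hypothesis is that these cells differ in myeloid state or clonal origin from WT, which the labels cannot test.

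Other splits of the same libraries were counted, with 10 splits per comparison, too few for a share under 0.05. For IRF2KO against WT, 2 of 10 splits gave as many genes as the real 48, the other being 483, and 1 of 10 as many lists (8, highest other 6). The split with 483 genes set WT replicates 1 and 2 and IRF2KO replicate 1 (mitochondrial share 12.2% to 12.9%) against the rest (17.1% to 18.8%), which points to a structure of the samples; with that share as a term 49 genes passed, and within its lower and upper side 38 and 26. For the libraries labelled pIRF2 against IRF2KO, 1 split gave as many genes (42, highest other 0) and 4 as many lists (3, highest other 5). Against WT, 1 split gave as many genes (9, highest other 0) and 1 as many lists (9, highest other 3). Of 100 regroupings of all libraries, 1, the real one, gave as many reverted genes (28, highest other 5), the smallest share they can give. That makes a chance regrouping unlikely for that count but does not exclude it. The count also takes the libraries as exchangeable, which their structure puts in doubt.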
